A study of Rattus norvegicus with 21 samples.

How the data were processed

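Synovium, the tissue that lines the joint, was taken from male Sprague-Dawley rats in 7 groups, and RNA-seq libraries of 3 samples per group gave 21 samples in all. Per the labels, each group had 10 rats, and knee osteoarthritis was induced by injecting 50 µL of monosodium iodoacetate (MIA, a compound that injures joint cartilage) at 40 mg/mL beside the patella, while the control group received saline. Libraries were made from 800 ng of RNA with a stranded mRNA kit, per the labels' protocols. Treatment ran for 14 days with 2 applications a day. The gel groups received Jingu Zhitong Gel at 1.24 (high), 0.62 (medium) or 0.31 g/kg (low). The groups labelled fu and qing are the ointment groups at 0.105 g/kg. The design text names Votalin and Qingpeng ointments, and that fu is the Votalin group follows only by elimination, so the labels fu and qing are used here. The labels do not say that the 3 libraries of a group came from separate rats, so p-values measure the spread between these libraries, which may be partly technical.

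The submitters' processing notes name HISAT2, featureCounts, Subread and DESeq2 and the genome build rn6, without versions or order. The deposited values are whole numbers, but they are not read counts. Each of the 21 columns sums to between 999675 and 999807. For the 7432 genes with a mean of 4 to 32, the median ratio of the variance within groups to the mean was 0.255, and 71.7% of these genes lay under 0.5, where counting alone would give a ratio of 1. The deposited values were therefore treated as a score, a per-million value that had been rounded to whole numbers. Whether it is a CPM (scaled to the reads) or a TPM (scaled also by gene length) cannot be told from the values, and the scaling and rounding steps are not given in the sources used here. The sequencing depth of each library is unknown, so no counting interval or detection floor is given, and a gene listed at 0 may have had reads. The rounding step of 1 limits the precision of low values. Between 14577 and 15114 genes per library had a value of at least 1, and the 10 most abundant genes held 13.9% to 18.7% of a library's total.

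Tests had been planned for read counts, before the data were examined, and were replaced because the values are not counts. All comparisons used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with trend and robust set) on log2(value + 1), in one model of all 21 samples with 7 group means. Of 32623 rows, 15126 were 0 in every sample, and the 16078 genes with a value of at least 1 in at least 3 samples were tested. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Counts of genes with an unadjusted p under 0.05 are given beside the calls. If no gene differed, a share of 0.05 of the genes tested would reach it on average, so these counts are not counts of differing genes. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Comparisons were the model group against control, each treated group against model and against control, the high dose against each ointment, and a linear trend over gel dose with the model group as dose 0. The procedure was tested on simulated data for the high dose against model, with real means and spreads over 16078 genes, 20 draws, and changes placed in genes with a typical value over 5. It recovered 52.1% of genes changed 1.5-fold, 83.3% of those changed 2-fold, 96.4% at 4-fold and 99.9% at 8-fold, and 5.77% of its calls were false. Each draw held 200 changed genes, 50 at each fold, with noise independent between genes and libraries. Where few genes truly differ the adjusted threshold is stricter, so recovery may be lower there and was not measured. Comparisons with few or no calls therefore do not exclude changes of these sizes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

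The values carry Ensembl rat gene identifiers without gene names. The reference table given for the rat (assembly GRCr8) holds no Ensembl identifiers, and 0 of the 32623 identifiers matched it. For this reason the 27 gene lists planned beforehand (among them IL-17 signalling and output genes, matrix proteases, and markers of macrophages, neutrophils, synovial fibroblasts and skeletal muscle) were not tested, and the genes that were to be reported in every comparison (such as the IL-17, IL-6 and matrix metalloproteinase genes) could not be looked up. The rule for named genes took those past the threshold whose libraries did not overlap between both groups and whose mean was at least 1 in one of them, in order of fold change. Because no names were at hand, at most 2 identifiers in each direction are given for a comparison. Where no gene passed, those with the smallest p were taken. The rule was set before the data were examined, and its other parts needed gene names.

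A score of each library on the axis from control to MIA was added after the data were seen. It is the mean over the genes called between the 18 MIA libraries and the 3 control libraries, each signed by its direction, scaled so that the control mean is 0 and the mean of the MIA libraries is 1. For comparisons that share libraries, unchanged groups were simulated in 100 draws by resampling the residuals of whole libraries. Replicate numbers are shared between groups in the labels, and a model with the number as a block was run as an alternative. Alternatives planned beforehand that need no counts or gene names were median-of-ratios scaling, no filter on low values, a model of only the groups compared, the replicate block, and each library left out in turn. Alternatives added after the data were seen were pseudocounts of 0.5 and 4, a mean of at least 10, sample quality weights, uniform noise of up to 0.5 either way for the rounding, and leaving out both libraries that stood apart. No pair of libraries held duplicate values, and Spearman correlations between libraries ran from 0.953 to 0.977.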

Results

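Gene expression in knee synovium was profiled in 7 groups of 3 rat libraries: saline-injected controls, untreated MIA rats (model), MIA rats given Jingu Zhitong Gel at a high, medium or low dose, and MIA rats given one of the ointments labelled fu and qing. The values are per-million values rounded to whole numbers, with column totals of 999675 to 999807 and an unknown sequencing depth. The title of the study places the question in IL-17 signalling. The values carry gene identifiers only, so IL-17 genes are not analysed here, and expression is described by numbers of genes and by a few identifiers whose gene names were not looked up.

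The model group against the control group asks what the MIA injection does to synovial gene expression. In the model group 1508 genes were higher and 1365 lower than in control, 2873 of the 16078 genes tested (17.9%, limma adjusted p under 0.05). Among these, 599 higher and 449 lower genes differed by at least 2-fold, and 99 and 76 by at least 4-fold. By mean value over all libraries, which the change itself helps to set, the share of called genes that were higher was 37.8% of 135 under a mean of 1, 58.2% of 402 at 1 to 5, 47.9% of 866 at 5 to 20, 49.4% of 1046 at 20 to 100 and 68.6% of 424 over 100; the shares followed no single order and were not tested. The gene with the largest rise, ENSRNOG00000043451, went from 2 ± 1 in control to 1330 ± 792 in the model group (SD, n = 3 each), a log2 difference of 8.58 (SE 0.968, limma adjusted p = 7.64e-05). ENSRNOG00000002548 went from 1 ± 1 to 293 ± 258 (SD, n = 3 each), a log2 difference of 6.99 (SE 0.694, limma adjusted p = 3.51e-05). Both had control values near the rounding step, so their folds are imprecise. ENSRNOG00000024923 fell from 949 ± 343 to 37.7 ± 13.2 (SD, n = 3 each), a log2 difference of -4.62 (SE 0.766, limma adjusted p = 0.000767). ENSRNOG00000051744 was listed at 0 in all 3 model libraries and at 50, 29 and 48 in the control libraries (limma adjusted p = 0.0381), a call that 7 of the alternatives did not keep; it was also at 0 in 10 of the 15 treated libraries, and no fold is given. The count of called genes dropped to 1496 without model 3, to 1693 without control 1 and to 1909 without control 2. Model 3 and low 1 stood apart from their groups together (residual correlation 0.347 across genes), and without both the count was 1509.

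**Figure D1:**
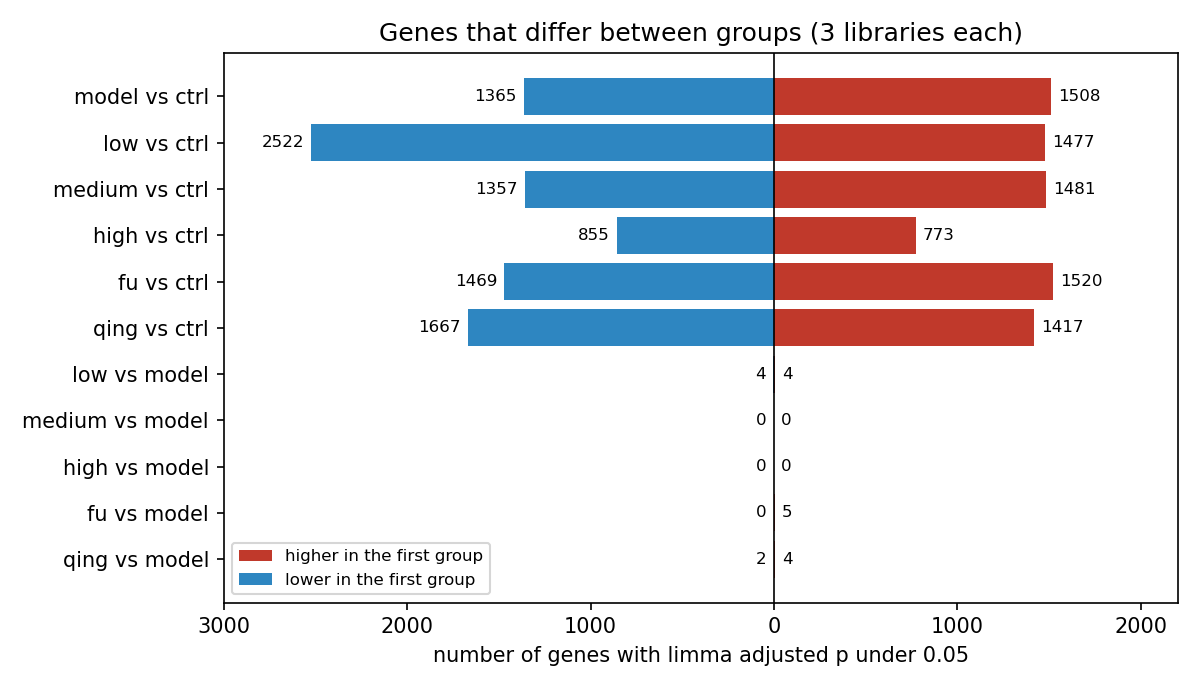
Number of genes with a limma adjusted p under 0.05 in each comparison (x axis, number of genes), higher in the first-named group to the right and lower to the left, 3 libraries per group. Counts against control ran from 1628 (high) to 3999 (low), and counts against the model group from 0 (high and medium) to 8 (low).

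The gel groups against the model group ask whether the gel changed expression in the injured synovium. At the low dose, 4 genes were higher and 4 lower than in the model group, and 1273 had an unadjusted p under 0.05. If no gene differed, a share of 0.05 of the 16078 genes tested would reach that p on average. ENSRNOG00000021027 was at 31 ± 6.08 in the model group and 235 ± 87.9 at the low dose (SD, n = 3 each), a log2 difference of 2.82 (SE 0.358, limma adjusted p = 0.0083). ENSRNOG00000018413 rose from 14.3 ± 3.51 to 45.7 ± 12.01 (SD, n = 3 each), a log2 difference of 1.60 (limma adjusted p = 0.0328). ENSRNOG00000013408 fell from 29.3 ± 8.39 to 4.33 ± 2.08, and ENSRNOG00000014448 fell from 29 ± 6.25 to 5 ± 2 (SD, n = 3 each, limma adjusted p = 0.0172 and 0.0328). Over the 16 alternatives these calls were lost in 3 for ENSRNOG00000021027 (limma adjusted p from 0.00301 to 0.259), 6 for ENSRNOG00000018413 (0.0168 to 0.429), 5 for ENSRNOG00000013408 (0.012 to 0.38) and 8 for ENSRNOG00000014448 (0.0165 to 0.342), and all 4 were lost when only the low and model libraries were in the model. At the medium dose no gene passed by limma, and 980 had an unadjusted p under 0.05. ENSRNOG00000021027 and ENSRNOG00000018413 had the smallest p there, with values of 164 ± 60.5 and 49.3 ± 16.6 (SD, n = 3 each, limma adjusted p = 0.0668 for both). At the high dose no gene passed by limma, and 903 had an unadjusted p under 0.05. The smallest limma adjusted p was 0.088, for ENSRNOG00000015117, at 1 in every high-dose library and 0 in every model library, the size of the rounding step. ENSRNOG00000062018, at 0 in high and 1.67 ± 0.577 in model, was also near that step (limma adjusted p = 0.112). ENSRNOG00000050188 lay well above it, at 29 ± 6.56 in high and 14 ± 2 in model (SD, n = 3 each). Its log2 difference was 0.986 (limma adjusted p = 0.149), and none of 16 alternatives called it. The difference was not particular to the high dose. The gene was at 23.7 ± 5.03 in low, 25.7 ± 5.51 in medium, 25 ± 1.73 in fu and 21.7 ± 2.08 in qing (SD, n = 3 each). In each it was above the same model libraries without passing (limma adjusted p from 0.216 to 0.333). ENSRNOG00000021027 stood at 51.3 ± 20.8 at the high dose (SD, n = 3), a log2 difference from model of 0.655 (SE 0.358, limma adjusted p = 0.887). The replicate block ended the low-dose call of ENSRNOG00000018413 (limma adjusted p = 0.0735), and median-of-ratios scaling that of ENSRNOG00000014448 (limma adjusted p = 0.0516). The 8 low-dose calls became 0 with only the groups compared, 13 with a mean of at least 10 and 16 with sample quality weights. Weights also called 12 genes at the medium and 3 at the high dose, and median-of-ratios scaling, a mean of at least 10 or only the groups compared called 2 at the medium dose. At the high dose a pseudocount of 0.5 called 2, and no low-value filter or only the groups compared called 1. The counts at these doses also rested on single libraries: for the low dose the 8 calls became 0 without low 3, 1 without model 2, 2 without model 1 and 4 without low 2. For the medium dose 4 genes passed without medium 2, and 1 each without model 1, model 2 or model 3. For the high dose 2 passed without model 2, and 1 each without model 1 or high 3.

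A linear trend over gel dose, from model through low and medium to high, called 1 gene, ENSRNOG00000015117, the gene that moved between 0 and 1. It had a slope of 0.829 log2 units per g/kg (limma adjusted p = 0.0351), and 1160 genes had an unadjusted p under 0.05. The gene was at 0 in every model, low and medium library and at 1 in every high and control library, a step at 1 dose and not a graded change. Its values did not vary within any group, so its p rests on the spread limma borrows from other genes. This call was lost in 15 of the 21 alternatives that tested the gene (limma adjusted p from 0.000906 to 0.346), among them leaving out any 1 library other than medium 2. The trend called 0 genes without each of model 3, high 1, high 2, medium 1, medium 3, low 1, low 2 and low 3, and 2 without model 2 or medium 2. Without model 1, model 2 or high 3, and with only the groups compared, the genes called did not include ENSRNOG00000015117. The trend also called 0 with the replicate block, where ENSRNOG00000015117 had a limma adjusted p of 0.147. The same held when noise of the size of the rounding was added, with a mean of at least 10, and without both model 3 and low 1. The trend called 2 with a pseudocount of 0.5 and 6 with sample quality weights.

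The ointments served as positive controls. Against the model group, fu had 5 genes higher and 0 lower, and qing had 4 higher and 2 lower. An unadjusted p under 0.05 was reached by 1179 genes in fu and 1859 in qing. ENSRNOG00000021027 was at 176 ± 56.1 in fu and 220 ± 58.6 in qing, and ENSRNOG00000018413 at 52 ± 7.81 and 67.7 ± 12.1 (SD, n = 3 each). Their log2 differences from model were 2.44 and 2.77 for the former gene and 1.80 and 2.17 for the latter (limma adjusted p from 0.00509 to 0.0191). ENSRNOG00000014448 was at 4.33 ± 0.577 in qing (SD, n = 3), a log2 difference from model of -2.47 (limma adjusted p = 0.0245), and at 6 ± 4.36 in fu, where it did not pass (limma adjusted p = 0.0639). ENSRNOG00000018516 was at 17.7 ± 1.15 in control, 29 ± 1 in model and 16.3 ± 2.31 in qing (SD, n = 3 each), a log2 difference from model of -0.80 in qing (limma adjusted p = 0.00848), lost in 5 of 16 alternatives (0.00517 to 0.124). In all, 9 genes were called in any treated group against the model group, and 4 of them, all higher, were called in the low dose, fu and qing alike. If the 3 lists were independent, 3.09e-07 genes higher in all 3 would be found, and none of 100 simulations of unchanged groups against shared model libraries gave a gene called in all 3, though the highest of them gave 14 genes called in 2 or more lists, against 6 observed over the treated groups. Neither value allows for both shared libraries and real effects, so part of the overlap may come from the shared model libraries. The control libraries argue against those as its whole source. The 7 genes called in fu or qing, which include these 4, had a mean signed shift from model of 0.188 ± 0.142 log2 units in control. It was 1.56 ± 0.304 in low, 1.54 ± 0.316 in fu and 1.72 ± 0.166 in qing (SD, n = 3 each). ENSRNOG00000021027 and ENSRNOG00000018413 were also called higher than control in low, fu and qing (limma adjusted p from 5.68e-05 to 0.0257). With only the groups compared fu had 1 call and qing 2. The call in fu was neither ENSRNOG00000021027 nor ENSRNOG00000018413 (limma adjusted p = 0.147 and 0.164). A pseudocount of 4 gave fu 8, and sample quality weights gave qing 11. The calls in fu were lost in 4 of 16 alternatives for ENSRNOG00000021027 and 6 for ENSRNOG00000018413, and those in qing in 1, 2 and, for ENSRNOG00000014448, 6. The replicate block left fu with 2 calls, without ENSRNOG00000018413 (limma adjusted p = 0.06). The fu count became 0 without fu 2, 1 without model 2 and 2 without model 1, and the qing count became 0 without qing 1. The genes called in fu without model 2 or model 1 were all lower than in model, whereas the 5 reported were all higher.

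**Figure D2:**
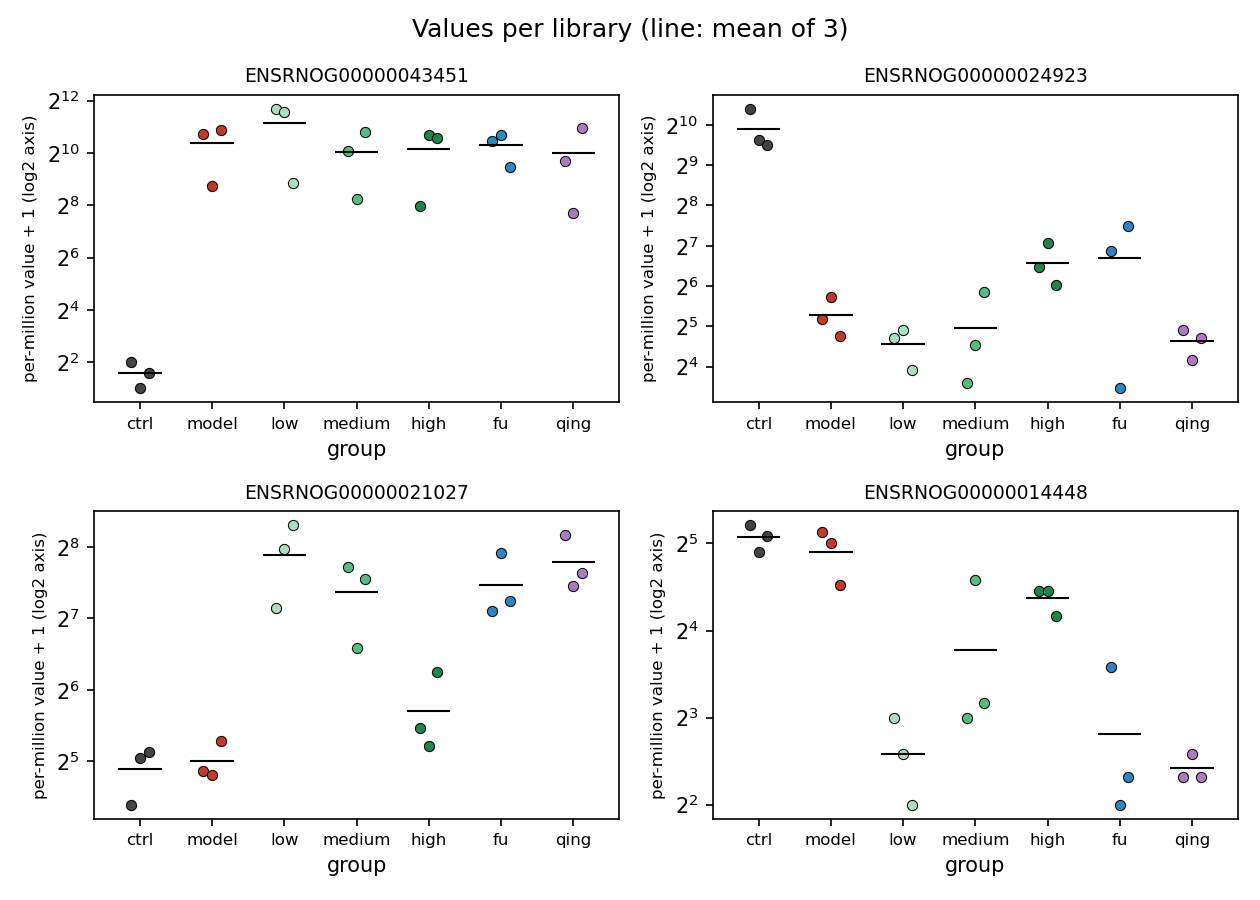
Per-million value plus 1 of 4 genes in each library (log2 y axis), by group (x axis), with points for single libraries and a line at the mean of 3. ENSRNOG00000043451 and ENSRNOG00000024923 separate control from all MIA groups, while ENSRNOG00000021027 has means of 28.7 in control, 31 in model and 51.3 in high against 235 in low, and ENSRNOG00000014448 means of 32.7, 29 and 19.7 against 5.

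The high dose against each ointment compares the gel with the positive controls directly, at different doses (1.24 against 0.105 g/kg). No gene passed in either comparison by limma. Genes with an unadjusted p under 0.05 numbered 1336 against fu and 1481 against qing. ENSRNOG00000021027, at 51.3 ± 20.8 in high and 220 ± 58.6 in qing (SD, n = 3 each), had a log2 difference of -2.11 (SE 0.358, limma adjusted p = 0.102). ENSRNOG00000062036 was at 10 ± 6.25 in high, 1.33 ± 0.577 in fu and 1 ± 0 in qing (SD, n = 3 each, limma adjusted p = 0.198 and 0.102). Without high 3 it passed in both (limma adjusted p = 0.000461 and 0.00017). ENSRNOG00000015117, ENSRNOG00000062018 and ENSRNOG00000003776, also listed by the rule, had values near the rounding step. The absence of calls depended on the setting: sample quality weights called 7 genes against fu and 29 against qing, a pseudocount of 0.5 called 2 against fu, no low-value filter called 1 against each, and only the groups compared called 1 against qing. Without high 3, 2 genes passed against fu and 4 against qing, and without qing 3, 1 passed against qing.

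Each treated group against control asks which genes differed from saline-injected synovium under treatment. The high dose had 773 genes higher and 855 lower than control (1628 in all), the medium dose 1481 and 1357 (2838), the low dose 1477 and 2522 (3999), fu 1520 and 1469 (2989), and qing 1417 and 1667 (3084), by limma. Under median-of-ratios scaling the low dose had 1962 higher and 2089 lower, so its surplus of lower genes depends on the scaling. In all 6 MIA groups 522 genes were higher and 607 lower than control. Independent lists would share 0.00511 and 0.0091 genes, and simulations of unchanged groups against the same control libraries shared 0 in each of 100 draws, a value that says little, since groups without effects leave few genes to share. With 3 control libraries the controls were not split, so part of the excess may come from them. Of the 2873 genes called in the model group, 1394 (48.5%) were called in the same direction at the high dose, 2040 (71.0%) at the medium dose, 2344 (81.6%) at the low dose, 2046 (71.2%) in fu and 1929 (67.1%) in qing, and 0 were called in the opposite direction. Independent lists of these lengths would share 145 genes at the high dose, 254 at the medium dose, 353 at the low dose, 267 in fu and 274 in qing. Simulated unchanged groups shared 0 in each draw, with the limit just given. These shares rest on the same control libraries, and the shortest list (high) gave the lowest and the longest (low) the highest, so they do not measure how much of the MIA difference remained. ENSRNOG00000043451 stood at 1138 ± 772 in high, 1059 ± 746 in medium, 2256 ± 1559 in low, 1262 ± 497 in fu and 1012 ± 906 in qing (SD, n = 3 each), ranges that overlap with the model group. ENSRNOG00000024923, at 949 ± 343 in control, stood at 94.3 ± 34.6 in high, 30 ± 24.02 in medium, 22.7 ± 7.77 in low, 102 ± 85.9 in fu and 23.7 ± 6.11 in qing (SD, n = 3 each), and no treated group differed from model past the threshold for this gene (limma adjusted p from 0.774 to 0.919). Counts dropped by over 1.5 times without control 1 (852 for high, 1675 for medium, 2662 for low, 1871 for fu, 2015 for qing) and without control 2 (948 for high, 1877 for medium). They also dropped without high 2 (1036), high 3 (929), fu 2 (1734) and qing 3 (1915). With sample quality weights the counts were 3334 for high and 4688 for medium. Whether the high dose differs from the other groups in its count was not tested by these lists.

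Whether treatment moved genes in the direction opposite to MIA was tested over all 16078 genes. Differences of a treated group from model correlate negatively with those of model from control through the shared model libraries alone. Simulated unchanged groups gave a covariance of -0.0539 (SD 0.0459, 100 draws) and a correlation across genes of -0.228. The simulated noise was added to observed differences of model from control, which already hold noise. That leaves the covariance usable but makes the simulated correlation too weak, so only the covariances are compared with the simulation. Observed correlations across genes, which are not independent replicates, were -0.517 (high), -0.256 (medium), -0.110 (low), -0.263 (fu) and -0.275 (qing). The covariance less the simulated one was -0.0516 for high, 0.00122 for medium, 0.0324 for low, -0.00144 for fu and -0.00857 for qing, and 13 of 100 draws were as low as the high dose. It depended on single model libraries: without model 3 the value was -0.0132 for high, and without model 2 it was -0.103 for high, -0.0453 for medium, -0.00444 for low, -0.0487 for fu and -0.0572 for qing. Of the genes called in the model group, 1 was called the other way at the low dose and 1 in qing, and 0 in high, medium and fu. In both it was ENSRNOG00000018516, higher in model than in control (log2 difference 0.686, limma adjusted p = 0.000805) and at 17.3 ± 2.08 in low (SD, n = 3, limma adjusted p = 0.0273). It was also below model in high (21.3 ± 0.577), medium (23.7 ± 3.21) and fu (21.3 ± 2.52) without passing (SD, n = 3 each, limma adjusted p from 0.436 to 0.779). All these differences rest on the same model libraries, so the calls in low and qing are not independent.

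On the axis from control to MIA, built on 4341 genes, of which 2078 were higher in MIA, the model group scored 0.994 ± 0.188, low 1.09 ± 0.0407, medium 1.02 ± 0.0233, high 0.85 ± 0.109, fu 1.02 ± 0.227 and qing 1.03 ± 0.123 (SD, n = 3 each). In exact permutation tests against model no treated group passed. For high the difference was -0.145 (exact p = 0.3, adjusted over 5 groups 0.9), and 3 libraries against 3 allow no exact p under 0.1. A permutation test over the 6 MIA groups together gave p = 0.468, and 1 gene differed among them in a limma F test, with 1322 genes at an unadjusted p under 0.05. Of 100 splits of the 18 MIA libraries, 11 gave at least 1322 such genes (highest other 2192), so chance is not excluded for that count.

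**Figure D3:**
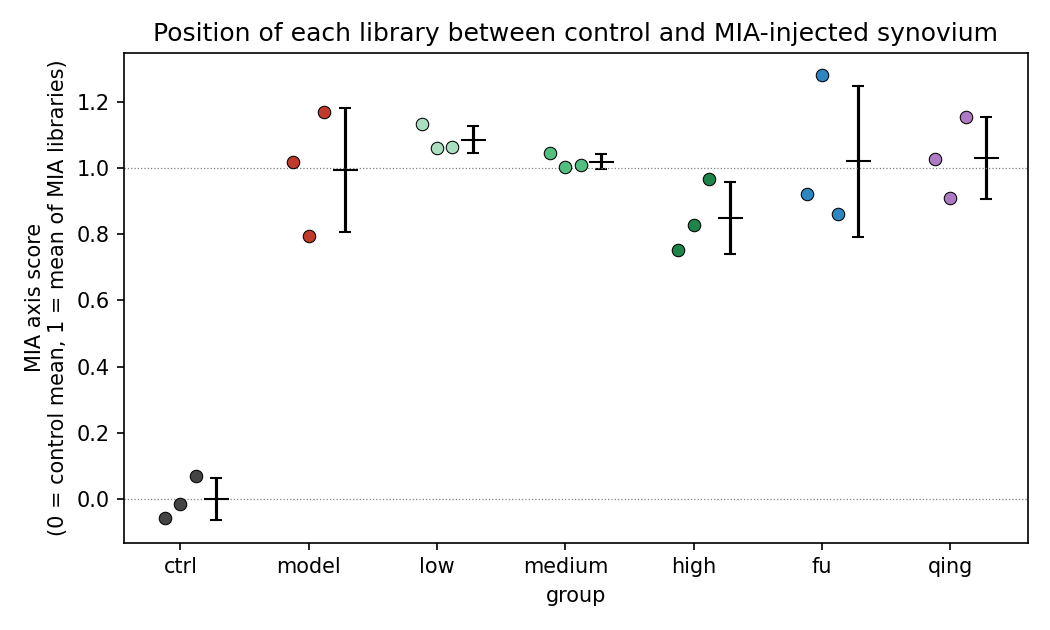
Score of each library on the axis from control (0) to the mean of the MIA libraries (1) on the y axis, by group on the x axis; points are libraries, and bars give the mean and SD of 3. All 18 MIA libraries lie between 0.752 and 1.28, and the high-dose libraries lie at 0.752, 0.829 and 0.968.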

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

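Pseudocounts, the mean filter, weights, rounding noise and the removal of model 3 with low 1 were chosen after seeing the data. Depth is unknown, so what it limits cannot be stated. DESeq2 and voom weights (which need counts), the muscle covariate and all gene-list alternatives (which need names) were not run. Every setting kept each identifier's direction: of 749 values, 638 stayed on their side of the threshold, 83 lost and 28 gained a call. Causes were not tested except where fewer samples or genes were used. The counts against model that moved by over 1.5 times follow. Median-of-ratios scaling gave medium 2. No low-value filter gave 1 for high against model, fu and qing. Only the groups compared gave high 1, medium 2, low 0, fu 1, qing 2, and high against qing 1. Pseudocount 0.5 gave 2 for high against model, 2 against fu and 2 for the trend, and pseudocount 4 gave fu 8. A mean of at least 10 gave medium 2, low 13 and trend 0. Weights gave high 3, medium 12, low 16, qing 11, trend 6, high against fu 7, high against qing 29, and against control high 3334 and medium 4688. Rounding noise gave trend 0. Without model 3 and low 1 the counts were 1509 for model against control, medium 3, low 4 and trend 0. The opposite-direction difference was also taken over the 2873 genes with the largest difference between model and control, as many as were called. It was -0.223 for high and 0.153 for low, on a wider simulated spread (SD 0.208). As over all genes, 13 of 100 draws were as low as the high dose, so the larger value is not a stronger result.

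Replicate numbers do not pair the libraries: 63 same-numbered pairs had a mean residual correlation of -0.013, 8 were over 0.1, and 6 of 21 libraries correlated best with their own number. The replicate block gave fu 2 and trend 0, left ENSRNOG00000018413 short of a call in low (limma adjusted p = 0.0735) and fu (0.06), and moved no other count by over 1.5 times.

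Leaving out each replicate gave 1496 to 2995 genes for model against control. Against model it gave 0 to 2 for high, 0 to 4 for medium, 0 to 7 for low, fu and qing, and 0 to 2 for the trend. It gave 0 to 2 for high against fu and 0 to 4 against qing. Against control it gave 852 to 1462 for high, 1675 to 2392 for medium, 2662 to 3471 for low, 1734 to 2737 for fu and 1915 to 2613 for qing. Opposite-direction differences ran from -0.103 to -0.0132 (high), -0.0453 to 0.0366 (medium), -0.00444 to 0.0521 (low), -0.0487 to 0.0356 (fu) and -0.0572 to 0.0276 (qing).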

Other observations

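Chosen after the result was seen were the tests on the 7 and 9 genes called in treated groups, on the axis score (of which the axis made without gel libraries was set before its own value was known), on the 6 MIA groups together and on the most abundant genes in model 3 and low 1, while the splits of each comparison and of the dose trend were not.

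The 9 genes called in any treated group against model hold 8 low-dose calls and no high-dose call, so their changes say nothing on dose. The 7 called in fu or qing, chosen by the ointment and model means with the spread of all libraries (6 were also called in low), had a mean signed shift from model of 1.56 ± 0.304 log2 units in low, 1.23 ± 0.43 in medium and 0.556 ± 0.184 in high, against 0.188 ± 0.142 in control (SD, n = 3 each). For these 7 genes, a gel effect that grows with dose is argued against as the whole cause by a shift that fell with dose over the 9 gel libraries (Pearson r = -0.846, exact p = 0.00833; Spearman rho = -0.843, exact p = 0.00952; leaving out 2 of the 3 high libraries, which are tied as the farthest in dose, gave r from -0.811 to -0.707). Adjusted over 4 relations computed on gel libraries, the exact p were 0.0167 and 0.0144. A candidate explanation is that groups were handled or collected at different times, which cannot be told apart from treatment, since the labels give no time or order (1 of the 9 genes was also called between model and control), and an effect common to low-dose gel and the ointments stays open, untested.

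The axis score fell from low to high gel dose over the 9 gel libraries (Pearson r = -0.87, exact p = 0.000595, the smallest that 1680 assignments can give; Spearman rho = -0.949, exact p = 0.00119; adjusted over the 4 relations, 0.00238 and 0.00476; r from -0.955 to -0.819 without 2 of the 3 high libraries). With the model group as dose 0, over 12 libraries, r was -0.524 (permutation p = 0.0805), rho -0.54 (permutation p = 0.0797) and r from -0.456 to -0.089 without 2 of the 3 high libraries, so its size depends on which of them are kept. That gel libraries shape their own axis is argued against by r = -0.85 on an axis made from control, model, fu and qing. What stays open is whether the gel may move the tissue towards control (high less model -0.145, with too few libraries to decide), chance (high against the 15 other MIA libraries, exact p = 0.0404 and 0.243 adjusted over 6 groups) and the group difference seen in the 7 genes called in fu or qing. The last cannot be told apart, because both follow the groups: the axis score and the mean signed shift of those 7 genes had r = 0.749 over the 9 gel libraries (rho = 0.817, exact p = 0.0133 and 0.0108, adjusted 0.0177 and 0.0144, r = 0.518 without the 2 farthest).

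Model 3 and low 1 deviated together from their groups (residual r = 0.347, the next highest pair between groups 0.248). Residuals were scaled up to allow for the fitted group means, so the raw deviations are smaller. Of 170 genes with a scaled residual over 1 log2 unit in the same direction in both, 155 were higher (91.2%, exact 95% interval 85.9 to 94.98). For 48 genes such residuals had opposite directions. The interval treats genes as independent, which they are not, so it is likely too narrow. No other pair of libraries was counted this way, so the share to be expected otherwise is unknown. Mostly higher genes are what RNA of another tissue in both libraries may give. Without gene names the tissue was not tested, and other shared programmes would do the same. A few genes taking most of the values is argued against, as the 10 most abundant genes held 14.5% and 17.5%, within the 13.9% to 18.7% of the other libraries. Whether model 3 hides differences from the model group cannot be told apart from few true differences: without it the count rose over 1.5 times in 1 of 5 comparisons (0, 1, 6, 6 and 7 genes for high, medium, low, fu and qing).

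Other splits of the 6 libraries of a comparison number 10 with the real one, too few for a share under 0.05. For model against control 1 split reached the real 2873 genes, and the highest other gave 8. Against control, 1 split each reached the real 1628 for high (highest other 2), 2838 for medium (2), 3999 for low (2), 2989 for fu (1) and 3084 for qing (2). Against model, 2 splits reached the real 8 for low (highest other 17), 2 the real 5 for fu (6) and 1 the real 6 for qing (3). For high and medium against model and for high against fu and qing the real count was 0, which all 10 splits reach, and the highest others gave 31, 1, 4 and 3. Whether the 31 genes of a mixed split of high and model libraries reflect a structure of the samples or chance was not tested. For the dose trend, 21 of 100 splits called at least the real 1 gene (highest other 4), and for a difference among the 6 MIA groups 40 of 100 splits called at least the real 1 gene (highest other 33), so chance is not excluded for either.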
